A study of Homo sapiens with 24 samples.

How the data were processed

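The series measured guide RNA inserts amplified from genomic DNA of H358 cells that expressed dCasRx-METTL3, in 24 sequenced samples made up of 3 replicates at each of 2 time points and 4 lanes per replicate. Per the series text the library was introduced at a multiplicity of infection near 0.3 and kept at a coverage of 400 cells per guide. Per the submitters' processing notes the reads were handled with Trim Galore, Bowtie2 and MAGeCK against hg38; versions and options are not given in the sources used here. Lanes were already joined in the deposited tables, which hold 3 values per time point.

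The deposited guide table holds, per the file headers, normalised read counts of the 3 libraries of each time point, with a further signal column per time point, deposited under the name of a mean, that equals the median of the 3 values for all but 4 guides. The authors also deposited a log2 fold change, a score and p-values with FDR per guide, per the file headers. The deposited gene table holds, per the file headers, a rank score, p-value, FDR and log2 fold change per target in each direction, and the log2 fold change equalled the median over guides for 2121 of 2124 targets. The control and treatment columns were read as day 0 and day 16 from that layout. The position of a value within a cell was not taken as a replicate number, and 0 columns of unmapped samples were present.

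Within a library the normalised counts were whole multiples of 1 value, so whole reads were recovered for 100% of values within 0.1 read. Totals were 7917059, 8888001 and 7936079 reads at day 0 and 5520607, 6726673 and 5491465 at day 16. These are PCR reads without molecular identifiers, so intervals and the limit of 3 reads for a count of 0 cover counting error only. Libraries of the same day differed by more than read counting gives (chi-square per degree of freedom 20.2 to 21.3 at day 0 and 5.79 to 6.67 at day 16), so none was treated as a repeat of another.

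Because the deposited values were normalised and joined within cells, the main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2(normalised count + 1), per guide and per target, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. A fold change on this scale understates the change of guides with few reads. A target is an entry of the Gene column, and its value in a library was the mean over its guides. Targets needed at least 3 guides, which left out 91 of 2124. Count models on raw counts were not used. As an alternative chosen after seeing the data, voom from limma was run on the recovered reads, which were summed over the guides of each target for the test of targets.

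Control guides were, by a list of names set before the data were examined, those named Scramble or eGFP (346 guides). That list held luciferase but not gLuc, so gLuc guides were left out of this set. The share of calls among control guides was compared with that of peak guides by Fisher's exact test, with Wilson 95% intervals, and their mean and SD by permutation with 10000 resamples. Gene lists were tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Of 17 lists, 11 had at least 5 targets and 3 had none. Lists were matched on the gene symbol of peak targets only. Positions are those in the guide names. Of 2074 targets with a position and a symbol in RefSeq GRCh38.p14, 2072 lay inside the named gene; exon and UTR annotation was not used here.

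Targets named in the text were, by a rule fixed in the same way, the 10 with the smallest p in each direction, the first 5 ranks in each direction of the authors' table, and in each list up to 4 members past the threshold in each direction by p, or the 2 with the smallest p where none passed, each with at least 3 guides (86 targets). Some of these targets, and lists that rest on them, are not reported here, though they stay in every count. Guides named in the text were chosen among those with the smallest p after their values were seen, as were TESC_con and CWC15_con. The ranks of Scramble_con, DNAH5_con and eGFP_con in the authors' table were also picked after they were seen.

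Alternatives fixed in advance were a pseudocount of 10, leaving out guides with a mean under 30, equal library totals, centring on control guides, the median over guides, at least 2 or 5 guides, a permutation over guides with 10000 draws, other thresholds for the authors' table and leaving out each library. Alternatives added later were voom, 1000000 draws for the permutation, and control sets with gLuc or with every con guide. The procedure was tested on simulated data of 12045 guides with 200 changed targets among 2033. Without guide-specific changes, the test across libraries recovered 100% of targets changed by 1 or by 0.5 on the log2 scale and called 0.382% of unchanged targets. With guide-specific changes given the SD of the observed log2 fold changes (0.60), it called 58.9% of unchanged targets, while the permutation over guides called 0.0546% and recovered 53% of targets changed by 1 and 4% of those changed by 0.5. The observed SD already held spread between libraries, which was added again at its median over guides. Of the real targets 44.1% were called, so the simulated shares do not carry over directly. The permutation used 10000 draws here, with which 1 changed target alone could not pass. Figures were drawn with matplotlib 3.10.9.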

Results

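Guide RNA abundance was measured in genomic DNA of H358 cells, an established human lung cancer line, that stably expressed dCasRx-METTL3. This protein joins a catalytically inactive RNA-targeting Cas13d to METTL3, the enzyme that writes N6-methyladenosine (m6A) on RNA, so that a guide RNA can bring the methyltransferase to a chosen transcript site. The pooled library held 12045 guides for 2124 targets. Of these, 2099 were m6A peaks in 1003 genes, taken by the study from prostate and lung cancer patients, with 10049 guides. The remaining 25 targets carried the mark con in the files: Scramble (196 guides), eGFP (150), gLuc (150) and 22 transcripts (1500). Cells were sampled after selection (day 0) and again after culture (day 16), with 3 replicates per day and 4 sequencing lanes per replicate already joined. Recovered reads per library ranged from 7917059 to 8888001 at day 0 and from 5491465 to 6726673 at day 16, with a median of 647 to 726 and 420 to 512 reads per guide. The labels did not state whether replicates came from separate cultures, so p-values across libraries measure only the spread between these libraries, which may be technical.

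Guide abundances were spread more widely at day 16 than at day 0. The Gini index, which is 0 when all guides are equally abundant, was 0.213 ± 0.00189 (SD, n = 3) at day 0 and 0.291 ± 0.000869 (SD, n = 3) at day 16, and all 3 day 16 libraries lay above all 3 day 0 libraries. The SD of log2 abundance over guides was 0.780 ± 0.00371 (SD, n = 3) at day 0 and 0.962 ± 0.00191 (SD, n = 3) at day 16. Each difference had a two-sided exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. Few guides were lost, with 2 to 5 guides at 0 in each library, where a count of 0 allows up to 3 reads. Across guides, which are not independent replicates, log2 abundances correlated at r = 0.879 to 0.884 between day 0 libraries, 0.959 to 0.961 between day 16 libraries and 0.727 to 0.733 between days. Rank correlation (Spearman's rho) was lower, at 0.749 to 0.755 between day 0 libraries, 0.945 to 0.947 between day 16 libraries and 0.556 to 0.565 between days.

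The comparison of day 16 with day 0 asks which guides were lost or gained while the cells grew. The direction was taken from the control and treatment columns of the deposited guide table, read as day 0 and day 16, which the labels did not state; if they were the other way round, every sign below would turn. Of 12045 guides, 5341 (44.3%) passed limma's test at an adjusted p of 0.05, 2698 lower and 2643 higher at day 16. The share of lower guides among those called was 50.5%, and it was 59.2% with equal library totals and 44.6% when centred on the control guides. Among the guides with the smallest p, 1 guide of AJUBA_peak2 rose from 34.5 ± 5.57 to 291 ± 51.8 normalised counts (SD, n = 3 per day). 1 guide of P3H4_peak1 rose from 284 ± 29.0 to 1463 ± 112, and 1 guide of MALAT1_peak1, on a long nuclear noncoding RNA, rose from 472 ± 73.9 to 2177 ± 122. In the other direction 1 guide of YTHDF1_peak2, on the transcript of an m6A reader, fell from 513 ± 53.3 to 103 ± 17.2. 1 guide of TTC21B_con, a con target, fell from 519 ± 61.2 to 69.0 ± 8.40. The authors' deposited guide table listed 1798 lower and 2593 higher guides at its FDR threshold of 0.05.

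Scramble and eGFP guides, the control set, changed at least as often as guides on m6A peaks. Of the Scramble and eGFP guides, 171 of 346 passed (49.4%, Wilson 95% interval 44.2 to 54.7%), against 4411 of 10049 peak guides (43.9%, 42.9 to 44.9%), an odds ratio of 1.25 (Fisher's exact p = 0.0473, two-sided, with guides taken as independent). Scramble guides passed in 50.5%, eGFP guides in 48.0% and gLuc guides in 43.3% of cases, and guides on con transcripts in 46.3%. The size of the difference from peak guides depends on which guides are taken as controls. With gLuc guides added to the control set, 236 of 496 passed (47.6%, Wilson 95% interval 43.2 to 52.0%). With every con guide, gLuc included, 930 of 1996 passed (46.6%, 44.4 to 48.8%). The shares of these wider sets were not tested against that of peak guides. The log2 fold change had an SD of 0.69 over the Scramble and eGFP guides and 0.60 over the peak guides (permutation p = 0.0009), while it was 0.55 over the gLuc guides and 0.66 with gLuc guides added to the control set. The mean of the Scramble and eGFP guides differed from that of the peak guides by -0.03 (permutation p = 0.381), and camera found no shift of this control set (p = 0.575, and p = 0.426 with an estimated correlation). Of the 25 con targets tested as targets, TESC_con (-0.30 ± 0.071, SE), IQCG_con (-0.27 ± 0.070) and CWC15_con (-0.18 ± 0.069) passed, all lower. Con targets held 20 to 300 guides each, against 5 for 1918 of all 2124 targets, and a mean over more guides varies less. A comparison of equal size was chosen after the result was seen. Of random groups of 5 Scramble and eGFP guides, a median of 49.3% met the p cutoff of called targets. The range was 37.7 to 62.3% over 100 draws, against 44.1% of all tested targets.

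**Figure D1:**
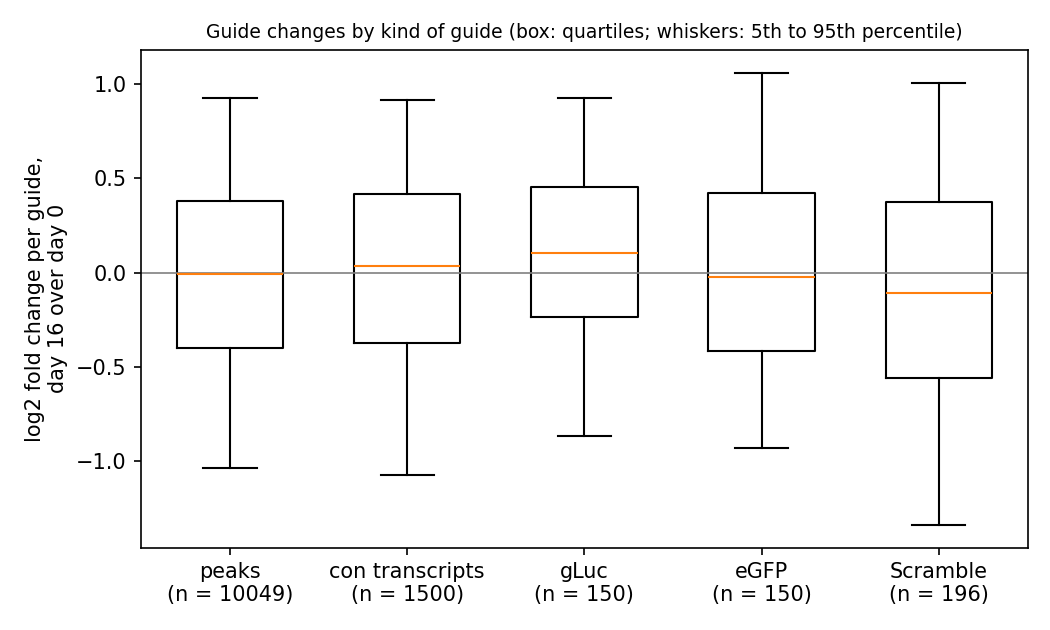
Log2 fold change per guide, day 16 over day 0 (vertical axis), for each kind of guide (horizontal axis), with boxes at the quartiles and whiskers at the 5th and 95th percentiles. The spread of the 196 Scramble and 150 eGFP guides was at least as wide as that of the 10049 peak guides.

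At the level of targets, guides on SPG11_peak2, in the transcript of the lysosomal protein spatacsin (chromosome 15, position 44584087, hg38), fell 2.11-fold on average (log2 -1.08 ± 0.081, SE, n = 3 per day). ZBTB7B_peak4, in the transcript of a zinc finger transcription factor (chromosome 1, 155016540), fell 2.04-fold (-1.03 ± 0.091). MOGS_peak1, in the transcript of a glucosidase that trims N-glycans (chromosome 2, 74461282), fell 1.72-fold (-0.78 ± 0.076), with all 5 guides lower. AJUBA_peak2, in the transcript of a LIM protein of Hippo signalling (chromosome 14, 22981461), rose 2.55-fold (1.35 ± 0.098). MYC_peak3, in the transcript of a growth-promoting transcription factor, rose 1.98-fold (0.98 ± 0.10) on 3 guides.

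Other targets among those with the smallest p in the lower direction were ANKRD40_peak7 (-0.93), YLPM1_peak3 (-0.78), CHERP_peak4 (-0.75), SEPHS1_peak1 (-0.71), DCAF5_peak2 (-0.70) and OXLD1_peak1 (-0.65). In the higher direction they were P3H4_peak4 (0.91), ZNF131_peak1 (0.89), KIF3B_peak1 (0.81), IQCE_peak2 (0.80), MRPL27_peak2 (0.75), MRM2_peak1 (0.74), ZNF703_peak1 (0.73) and HSPA13_peak1 (0.68). KIF3B encodes a motor subunit of kinesin-2, and MRPL27 a protein of the mitochondrial ribosome. For these 19 targets limma's adjusted p ranged from 9.61e-07 to 2.15e-05. All 5 guides were higher for P3H4_peak4, ZNF131_peak1, KIF3B_peak1, IQCE_peak2, MRPL27_peak2 and MRM2_peak1, while SPG11_peak2 and ZBTB7B_peak4 each had 4 guides lower and 1 higher. Other peaks of the same gene often moved differently. Of 8 MYC targets 4 rose, 2 fell and 2 did not pass, and of 5 HSPA13 targets 3 rose, 1 fell and 1 did not pass.

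**Figure D2:**
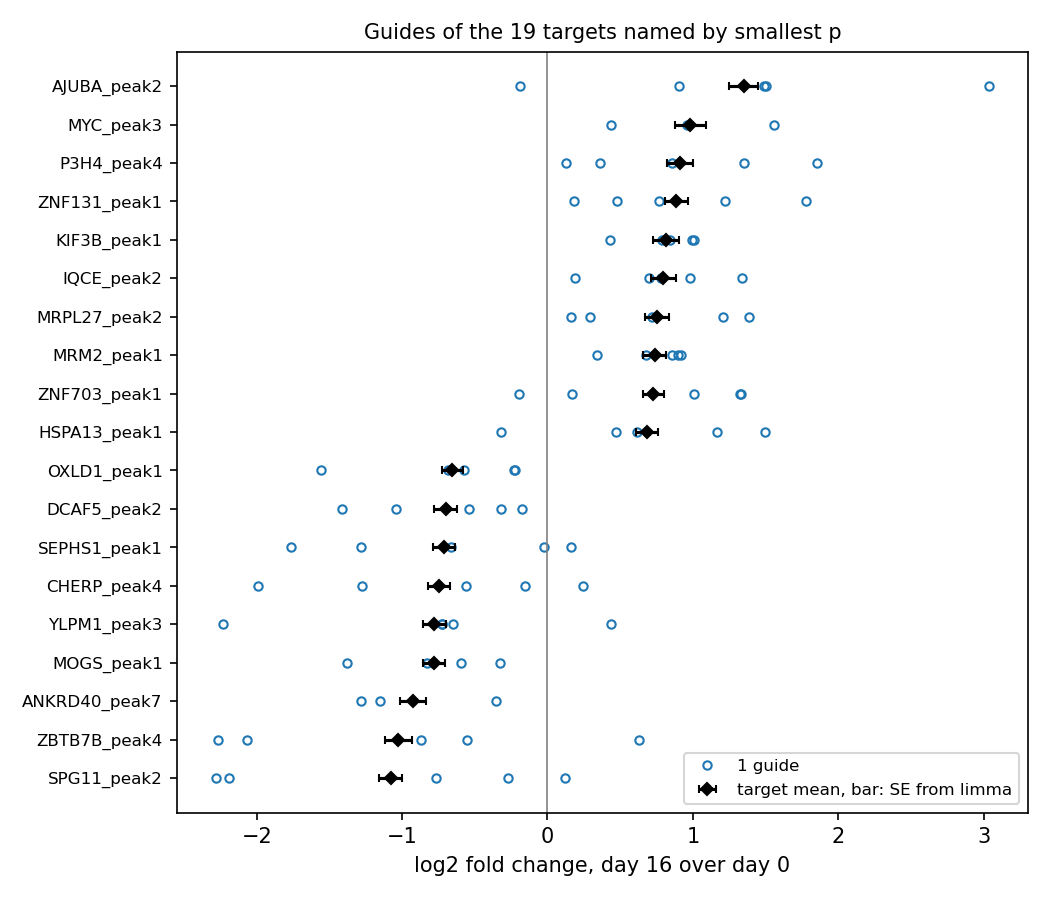
Log2 fold change, day 16 over day 0 (horizontal axis), of the 19 targets named by smallest p (vertical axis), with 1 circle per guide and a diamond and bar for the target mean and its SE. Target means ran from -1.08 for SPG11_peak2 to 1.35 for AJUBA_peak2, and the guides of a target lay much farther apart than its SE.

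Of 2033 targets with at least 3 guides, 897 (44.1%) passed limma's test across libraries, 493 lower and 404 higher, and 76 lower and 62 higher targets changed by more than 0.5 on the log2 scale. Rescaling to equal library totals moved the share of lower targets among those called from 55.0% to 73.3%, and centring on the control guides moved it to 42.5%. This test treats the guides of a target as fixed: the median SE of a target was 0.079, while the median SD over its guides was 0.53. Guides on the same target moved together about as often as chance gives. Of 1918 targets with 5 guides, 123 (6.41%) had all 5 on the same side of 0, against 6.25% by chance. Against random draws of as many guides, no target passed with 10000 draws, which are too few for any 1 target alone to pass. At an unadjusted permutation p under 0.05 there were 110 targets, where chance gives 101.65. With 1000000 draws, chosen after the first count was seen, AJUBA_peak2 alone passed (adjusted permutation p = 0.0163), and 106 targets had an unadjusted permutation p under 0.05. 4 of the 5 AJUBA_peak2 guides had few reads at day 0, from 8 to 51 per library, and its mean was 1.35 with an SD over guides of 1.17. Without its most changed guide, a removal that lowers the mean by construction, the other 4 averaged 0.93 with an SD of 0.80 and an unadjusted permutation p of 0.00247, which does not pass over 2033 targets.

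In the authors' deposited gene table, which ranks targets by how their guides are placed among all guides, SPG11_peak2 was the most depleted target (p = 0.000254, FDR 0.540). HSPA13_peak5 (p = 0.000902), TRAK2_peak2 (p = 0.00107), ZBTB7B_peak4 (p = 0.00153) and IQCG_con (p = 0.00603) followed in the authors' deposited table. The most enriched target there was ZFP36L2_peak1 (p = 0.000296, FDR 0.454), in the transcript of a protein that promotes decay of AU-rich mRNAs. ZNF703_peak1 (p = 0.000552), KIF3B_peak1 (p = 0.000641), RAB40C_peak1 (p = 0.00103) and GATC_peak1 (p = 0.00134) came next in the authors' deposited table. No target of the authors' deposited table had an FDR under 0.05 in either direction, nor under 0.25. At an unadjusted p under 0.05 the authors' deposited table held 110 depleted and 120 enriched targets among 2124, where chance gives 106.2 in each direction.

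Gene lists fixed before the data were examined described which kinds of transcript the called targets belonged to. Members are counted by the test across libraries, which 44.1% of all tested targets passed. The share that passed was 56.5% for the m6A machinery. Among the lists tested with camera it ran from 14.3% for DNA replication and mitosis (7 targets in 2 genes) to 73.3% for apoptosis (15 targets in 6 genes). These shares were not tested against 44.1%. Lists share genes, so their counts are not separate. EIF3A is in the m6A and translation lists, and BCL2L1 and MCL1 are in the oncogene and apoptosis lists. With 1000000 draws the permutation over guides called no list member except AJUBA_peak2. Among targets in transcripts of the m6A machinery, 7 of 23 fell, 6 rose and 10 did not pass, or 9 and 6 when adjusted over the list alone. YTHDF1_peak2, in a cytoplasmic m6A reader, fell (-0.65 ± 0.077, SE, n = 3 per day), as did EIF3A_peak4 (-0.63 ± 0.078). YTHDF3_peak1 (0.54 ± 0.073) and YTHDF2_peak3 (0.46 ± 0.074), in 2 further readers, rose, as did WTAP_peak1 (0.25 ± 0.071), in a subunit of the methyltransferase complex. ZC3H13_peak2 fell (-0.35 ± 0.091) as a mean over its guides, and with the median over guides its sign turned (0.26, adjusted p = 0.0705, limma).

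Growth signalling oncogenes held 32 targets, of which 10 fell, 9 rose and 13 did not pass, or 10 and 10 adjusted over the list alone. BCL2L1_peak3 (-0.59 ± 0.074) and BCL2L1_peak4 (-0.48 ± 0.075), in the transcript of a protein that blocks apoptosis, fell, and so did ERBB2_peak1 (-0.40 ± 0.085). MYC_peak8 (0.50 ± 0.077), MDM2_peak2 (0.51 ± 0.072) and MCL1_peak1 (0.51 ± 0.10) rose. Of 15 apoptosis targets, 7 fell and 4 rose, with the same counts adjusted over the list alone. BCL2L1_peak1 rose (0.38 ± 0.079) while 3 other BCL2L1 targets fell. In the transcript of the death receptor TNFRSF10A, 3 of 5 targets fell and 2 rose.

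Tumour suppressors held 62 targets, of which 14 fell, 18 rose and 30 did not pass, with 14 and 18 adjusted over the list alone. KMT2D_peak5, in a histone methyltransferase, rose (0.58 ± 0.080), as did BTG1_peak1 (0.48 ± 0.074), and NOTCH2_peak2 fell (-0.48 ± 0.074). Among 67 targets of chromatin regulators 13 fell, 19 rose and 35 did not pass, with 13 and 19 adjusted over the list alone. These counts largely repeat those of the tumour suppressors, since ARID1A (17 targets), KMT2D (16) and SETD2 stand in both lists. KMT2D alone had 7 targets higher and 1 lower. BAZ1B had 3 targets, all higher, led by BAZ1B_peak3 (0.47 ± 0.074), whereas BPTF had 3 of 6 targets lower and none higher, led by BPTF_peak1 (-0.40 ± 0.071). ARID1A, which encodes a subunit of the SWI/SNF remodelling complex, had 6 of 17 targets lower and 4 higher.

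In the translation and transcription core, 7 of 25 targets fell, 6 rose and 12 did not pass, with 7 and 6 adjusted over the list alone. EIF4G1, a scaffold of translation initiation, had EIF4G1_peak3 higher (0.56 ± 0.075) and EIF4G1_peak1 lower (-0.50 ± 0.077). Of 6 spliceosome targets 2 rose and 1 fell, as they did adjusted over the list alone. PRPF4_peak3 (0.58 ± 0.079) and PRPF4_peak1 (0.47 ± 0.074), in the transcript of a U4/U6 protein, rose with all 10 guides higher, and SNRNP70_peak1 fell (-0.38 ± 0.086). The 7 DNA replication and mitosis targets lay in 2 genes, with 6 of them in CLSPN. Of these 7, CLSPN_peak2 alone passed (-0.28 ± 0.075), also adjusted over the list alone.

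Hippo and YAP genes held 11 targets, of which 5 rose, 1 fell and 5 did not pass, or 5 and 2 adjusted over the list alone. Besides AJUBA_peak2, YAP1_peak1 (0.33 ± 0.073), in the transcriptional coactivator of the pathway, AJUBA_peak1 (0.28 ± 0.076) and CCN1_peak1 (0.24 ± 0.087) rose, and FAT1_peak3 fell (-0.26 ± 0.079). Of 13 glycolysis and hypoxia targets 3 fell, among them DDIT4_peak3 (-0.40 ± 0.072) and SLC2A1_peak1 (-0.27 ± 0.090), and 3 rose, among them EGLN1_peak3 (0.30 ± 0.083), with 3 and 3 adjusted over the list alone.

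The following lists, with fewer than 5 targets, were described without a set test. SRXN1_peak1 fell (-0.39 ± 0.086) and KEAP1_peak1 rose (0.27 ± 0.072) among 4 NRF2 and ferroptosis targets, where 3 fell and 1 rose adjusted over the list alone. ZEB1_peak1, the 1 target of the EMT list, stood at -0.21 ± 0.087 and did not pass over all targets (adjusted p = 0.0648, limma). With 1 target, adjustment over the list alone leaves the p-value unadjusted, so it decides nothing here. Ribosomal proteins, proteasome subunits and lung epithelial genes had no target in the library.

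None of the 11 lists tested with camera passed, with the preset or with an estimated correlation, and 1 list, not reported here, had an unadjusted p under 0.05. Hippo and YAP had a median log2 fold change of 0.09 (camera p = 0.0708, adjusted p = 0.390, and adjusted p = 0.688 with an estimated correlation). The smallest adjusted p of the other 9 lists described was 0.671. Mean and median differed in sign for 5 lists with values close to 0: DNA replication and mitosis, growth signalling oncogenes, tumour suppressors, chromatin regulators, and glycolysis and hypoxia. The camera direction was up for the translation list, whose mean and median were below 0.

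**Figure D3:**
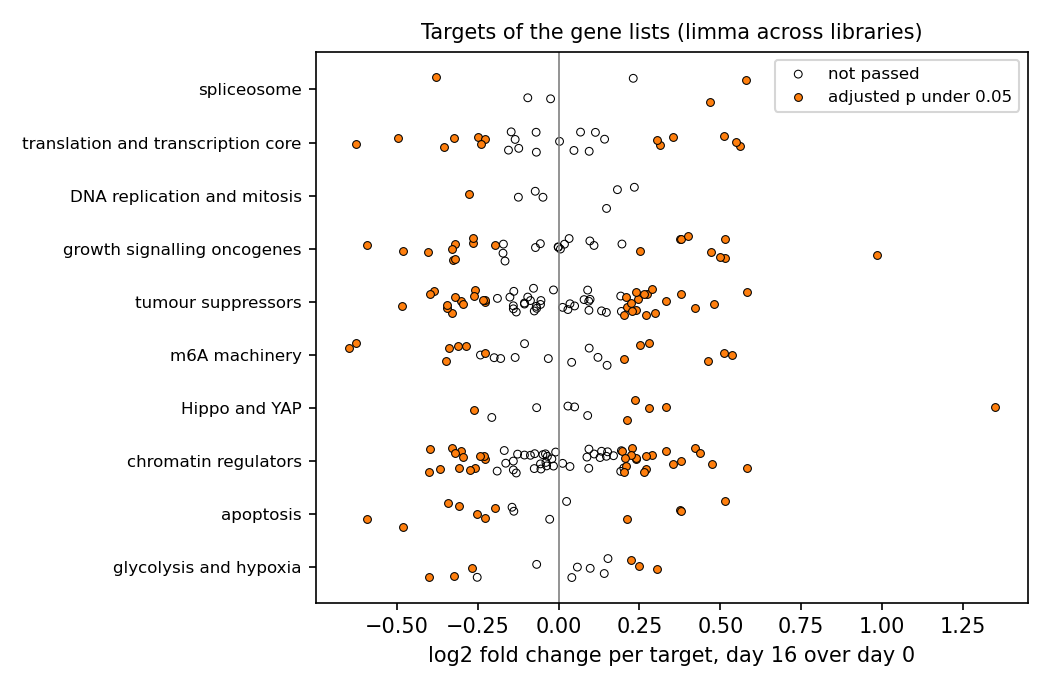
Log2 fold change per target, day 16 over day 0 (horizontal axis), for 10 gene lists with at least 5 targets (vertical axis), with filled circles for targets past an adjusted p of 0.05. Called targets lay on both sides of 0 in every list drawn except DNA replication and mitosis (1 lower).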

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

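Among the alternatives below, voom, the permutation with 1000000 draws and the wider control sets were chosen only after the result was seen. No paired analysis was possible because the joined values carry no replicate numbers, and a count test with DESeq2 was planned only for raw counts and was not run. The permutation over guides called 0 lower and 0 higher targets with 10000 draws, too few for any 1 target to pass, and 0 lower and 1 higher with 1000000 draws, against 493 and 404 across libraries, since it counts guides in place of libraries. With equal library totals 710 lower and 259 higher targets were called. The pseudocount of 10 moved the rise in the SD of log2 abundance from 0.182 to 0.178, and leaving out guides with a mean under 30 moved it to 0.192. At an unadjusted p under 0.01 the authors' deposited table held 18 depleted and 33 enriched targets, fewer because the threshold is stricter, where chance gives 21.24 in each direction. Without 1 library, 2145 to 2559 guides were lower and 2009 to 2531 higher, 380 to 488 targets were lower and 302 to 381 higher, and 0 lists passed. Of the 897 targets called, 674 to 774 were called again without 1 library and 707 with voom, which called 336 lower and 606 higher. The voom setting also changed the value of a target, from a mean of log2 values to summed reads, so the 2 changes cannot be told apart. List means that did not pass changed sign as follows. With equal totals they were -0.0703 for DNA replication and mitosis, -0.0543 for oncogenes, -0.0677 for tumour suppressors and -0.0484 for chromatin regulators. With the median over guides they were -0.0315 for oncogenes, -0.00340 for chromatin regulators and 0.00688 for glycolysis and hypoxia, which was 0.00206 with the pseudocount of 10. Without 1 library DNA replication and mitosis ranged from -0.00253 to 0.0234 and glycolysis and hypoxia from -0.0123 to 0.00446. Of the 85 named targets that passed, 19 no longer passed with the median over guides, 5 with equal totals, 2 with centring on control guides, 3 to 7 without 1 library and 85 with 10000 permutation draws. ZC3H13_peak2 turned to 0.26 with the median over guides and 0.13 with voom; the cause was not tested. The median log2 fold change of the control guides was -0.0582, with an SD of 0.0242 between libraries of a day. It was -0.135 with equal totals, -0.0162 with gLuc added and 0.0190 with every con guide, each a move beyond that spread. That spread is for a fixed set of guides and does not measure how the median varies with the guides chosen. A difference between the control sets was therefore not shown. The other counts kept within 1.5 times. The spread of guides around their target (median SD 0.53) limits what the test across libraries shows about a target.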

Other observations

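The tests of shuffled guides, of read counting, of reads at day 0, of a shared culture and of AJUBA_peak2 were chosen only after the result was seen, as was the variance ratio over abundant guides; the criterion for the AJUBA_peak2 test without 1 guide was set after its value was seen. Taking all guides of a gene together gave 1 gene of 1003 past an adjusted permutation p of 0.05, AJUBA (0.81 over 10 guides, 8 higher, adjusted p = 0.0401), in a test written before its result. It is not separate from AJUBA_peak2, which holds 5 of these guides; the other 5, of AJUBA_peak1, averaged 0.28 (unadjusted permutation p = 0.259). At an unadjusted permutation p under 0.05 there were 47 genes, where chance gives 50.15. The next 6 genes by p did not pass (adjusted p = 0.699 to 0.700). In order, GATC stood at 0.59 with 8 of 10 guides higher, KIF3B at 0.81 with 5 of 5 higher, GRWD1 at 0.54 with 9 of 10 higher, ASB7 at 0.53 with 6 of 10 higher, PRPF4 at 0.52 with 10 of 10 higher and OXLD1 at -0.45 with 13 of 15 lower.

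Many targets passed the test across libraries although guides of a target rarely moved together. Shuffling guides among targets gave a median of 910.5 called targets (849 to 990 over 100 shuffles) against the real 897. Random groups of 5 Scramble and eGFP guides were called in a median of 49.3%, against 44.1% of real targets. Changes of single guides unrelated to their target may therefore account for most calls. Read counting alone is argued against by a chi-square per degree of freedom of at least 47.3 between days. Libraries of the same day already exceeded read counting (20.2 to 21.3 at day 0 and 5.79 to 6.67 at day 16), so this outcome was to be foreseen. Sampling of few cells per guide as the whole cause would give a slope of guide variance on abundance near -1. The slope was -0.363 (95% interval -0.423 to -0.298). Abundance was taken from a single day 0 library, and error in it flattens the slope by an amount that was not measured. The slope therefore argues against this cause only as far as that error is small. For a biological effect on the targeted transcript, the variance ratio between genes over their target means was 1.05, inside the shuffled range of 0.845 to 1.18, which argues against a gene-wide effect as the source of most calls. Effects at single sites stay open, since the variance ratio of guides within targets was 1.05 (one-sided permutation p = 0.0783) and 1.11 for guides above the median abundance (p = 0.00750).

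Day 16 libraries were closer to each other than day 0 libraries, with a median SD within a guide of 0.14 against 0.21 on the log2 scale. Fewer reads at day 0 are argued against, since the smallest day 0 library held 1190386 more reads than the largest day 16 library. Sampling of few DNA templates at day 0 cannot be told apart from other sources, because the slope of excess variance on abundance was -0.498 (95% interval -0.554 to -0.450) and spans the bound of -0.5 set beforehand. A single culture or DNA pool behind the day 16 libraries may also contribute and stays open: a chi-square per degree of freedom of at least 5.79 excludes only repeat sequencing of 1 library, and the labels do not say how replicates were kept. No biological explanation was tested.

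AJUBA_peak2 was the 1 target to pass the permutation over guides. Guides with few reads could vary more widely. Sets drawn from the 100 guides nearest in day 0 abundance did not reach the mean of AJUBA_peak2 in 200000 draws (one-sided permutation p = 5.00e-06, the smallest they can give). Multiplied by the number of targets tested, this p was 0.0102. Only 58 to 64 guides per day 0 library lay under 30 normalised counts, so sets matched to its lowest guides also held more abundant ones. The draws therefore cannot exclude a wider spread of guides with few reads. The 121 other guides under 60 normalised counts had a median of -0.22 and an SD of 0.75, wider than the 0.60 over all guides. How far the call rests on its most changed guide (log2 3.04) stays open: the other 4 averaged 0.93 with an unadjusted permutation p of 0.00247, but removing a guide picked by its change lowers the mean by construction. An effect of the targeted AJUBA site may remain as a hypothesis, found and tested on the same data.

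Of the 10 splits of the 6 libraries into 3 against 3, the real one called 5341 guides and 897 targets and the highest of the others 0 and 0. No list passed in the real split, with 0 as the highest of the others, so that all 10 splits were as large; for guides and targets 1 of 10 was. The splits are too few for a share under 0.05.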
